A study of Mus musculus with 140 samples.

How the data were processed

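Small RNA was sequenced from 140 kidney samples of 28 mice, 5 samples per mouse. Libraries were made with a RealSeq library preparation kit, per the labels' protocols. Per the submitters' processing notes, FastQC 0.11.9, MultiQC 1.10, cutadapt 3.3 and Bowtie 1.3.0 were used, and the genome builds GRCm38.p6 and GRCm39 were named. Which build served which step, the mismatches allowed, the treatment of reads that match several miRNAs and the counting tool are not given in the sources used here. A read that fits several near-identical miRNAs may therefore have been counted for each, and such copies are reported as uncertain.

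The authors deposited one table of raw counts, whole numbers of reads per mature miRNA and sample, with no normalization. Each of the 140 columns was matched to its sample by name, and 0 columns of per-sample values were left unmatched. The table has 1474 miRNAs and 10 entries whose names start with # and name no miRNA, and what those entries hold is not given in the sources used here. They took a mean of 97.9% of all counts in peritubular capillaries, 87.2% in post-capillary venules, 84.7% in arterioles, 78.1% in glomeruli and 5.58% in whole kidney. They were left out of library sizes and tests. No 2 libraries had identical counts, and all libraries were used as separate samples.

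Column names come in 2 styles. The healthy and 4 h mice (12 mice, 60 libraries) have a dot in the name and the 24 h and 72 h mice (16 mice, 80 libraries) have none. The makeup of the # entries differed between these sets without overlap: the entry #I took 82.5% to 85.6% of their counts in the first set and 75.3% to 80.4% in the second, and #K took 11.4% to 14.1% and 15.2% to 19.3%. Each comparison of CLP with sham lies within one set, as do the comparisons among healthy compartments. Sham against healthy, and comparisons between 4 h and later times, cross the sets.

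Group, compartment, time and replicate number were taken from the sample labels. The replicate is the mouse, and the labels call the replicates biological. For each compartment, edgeR 4.0.16 (R 4.3.3) was fitted to the 28 libraries of its 7 groups, with TMM scaling and filterByExpr (minimum count 10, minimum total count 15), and CLP was compared with sham at each time by the quasi-likelihood F test. All 7 groups share one estimate of the spread, since each has 4 mice. Tests within mice used the 112 microdissected libraries with the mouse as a block: each compartment against the mean of the other 3 in healthy mice, and an F test with 3 degrees of freedom of whether the CLP effect differs between compartments. Whole kidney was compared with the 4 microdissected compartments in the 20 healthy libraries. Sham against healthy and the change of the CLP effect with time were tested with limma 3.58.1 (trend, robust) on the mean of log2 CPM (prior count 2) over the 4 microdissected compartments of each mouse. P-values were adjusted by the Benjamini-Hochberg method within each comparison, with 0.05 as the threshold, and are two-sided.

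CPM values are counts scaled with TMM to the miRNA counts of each library, given as mean ± SD of 4 mice. Log2 fold changes and their standard errors come from the fitted models. A fold against a group with 0 counts was computed against a floor of 3 counts over the whole group. A log2 fold change compares TMM-scaled miRNA counts. These need not follow the plain shares of miRNA counts, and they state no amount per cell.

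The named miRNAs were, in each comparison, up to 10 higher and 10 lower ones with the smallest p among those past the threshold, or the 2 with the smallest p where none passed, and the members of 18 fixed miRNA lists. The lists are endothelial, smooth muscle, tubular (miR-192, miR-194, miR-215), miR-200 family, miR-30 family, leukocyte, erythroid, inflammation, injury and fibrosis, hypoxia, miR-29 family, 17-92 cluster, let-7 family, Dlk1-Dio3 cluster, Hox cluster, hepatocyte, striated muscle, and neuronal and endocrine. Lists with at least 3 tested members were tested with fry, and its p was adjusted over all lists and comparisons of a family. fry tests whether the members move one way on balance and does not compare them with other miRNAs. The groups, tests, lists, the rule for naming and most alternatives were fixed before the data were examined. Chosen later were the per-mouse averages of CLP against sham, the scaling to the # entries, the fits that leave out one venule library, the counting of near-identical copies once, and the comparisons within or across the sets of column names.

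The alternatives were DESeq2 1.42.0 in place of edgeR, its RLE size factors in place of TMM, no filter on low counts, a prior count of 0.5, fits with or without the replicate number or mouse as a block, the spread from the compared libraries alone, leaving out libraries under 1e+05 miRNA counts, and leaving out each replicate in turn. Gene positions are from the RefSeq and GENCODE annotations of GRCm38.p6, 1 of the 2 builds the submitters name.

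The scripts were tested on simulated counts with 10% of miRNAs changed, 5 times per comparison. They were drawn from the real library sizes and the real mean of each compartment. For healthy glomeruli and healthy whole kidney, 1 common mean replaced those of the compartments. No effect shared by the libraries of a mouse was simulated. In the real data 44.2% of miRNAs were called for healthy whole kidney and 21.4% for glomeruli, so the false rates need not hold there. At 24 h of CLP against sham, 2-fold changes were recovered in 77.2% of cases in whole kidney, 29.1% in glomeruli, 17.4% in venules, 15.9% in arterioles and 13% in peritubular capillaries, and 4-fold changes in 93%, 57.1%, 38.2%, 47.7% and 36.7%. False calls made up 3.85%, 9.21%, 2.56%, 4.55% and 7.69% of calls. For the test between compartments at 24 h, 18.5% of 4-fold and 44.7% of 16-fold changes were recovered, with 12.7% false calls. For healthy glomeruli 44.4% of 4-fold and 73.6% of 16-fold changes were recovered (5.45% false), for healthy whole kidney 29.8% of 2-fold and 77.2% of 4-fold changes (3.17% false), for the time test 20.8% and 55.1% (1.43% false), and for sham against healthy 41.3% and 83.3%. In that last comparison 18.8% of calls were false (25 of 133), above the 5% aimed at, and the sham libraries mostly hold more miRNA counts than the healthy ones.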

Results

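The data set holds 140 small RNA libraries from kidneys of 28 male wild-type mice of the C57BL6/OlaHsd strain. Each mouse gave 5 libraries: arterioles, glomeruli, peritubular capillaries and post-capillary venules, which were collected by laser microdissection, and whole kidney, which was not microdissected. The mice fell into 7 groups of 4. One group was healthy and sampled at 0 h, 3 groups had a sham operation and were sampled at 4 h, 24 h or 72 h, and 3 groups had cecal ligation and puncture (CLP), an operation that lets gut bacteria into the abdomen and causes sepsis, and were sampled at the same times. The stated purpose was to find how the microRNAs (miRNAs) of the renal microvessels respond to acute kidney injury in sepsis. The table lists 1474 mature miRNAs and 10 further entries whose names start with #, which name no miRNA.

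The number of miRNA counts differed widely between compartments. The total miRNA count per library ranged from 1412288 to 7921184 in whole kidney, from 77258 to 1352025 in glomeruli, from 19307 to 569283 in arterioles, from 15148 to 567040 in post-capillary venules and from 4215 to 49456 in peritubular capillaries. In a single library, 0 counts allow up to 712 CPM (counts scaled to library size) in the peritubular capillary library with the fewest and up to 2.12 CPM in the whole kidney library with the fewest (3 counts of the total). Such limits, and the intervals given for single libraries, cover counting error only. The healthy and 4 h mice also had fewer miRNA counts than the 24 h and 72 h mice: the median miRNA count of the arteriole libraries was 91707.5 in the 12 former mice and 296676.5 in the 16 latter, and in whole kidney it was 2212450.5 and 5026386.5. In arterioles this was not for fewer counts in all, whose median was 3539272 in the former and 1382912.5 in the latter. The # entries took a mean of 97.4% and 75.1% of them in arterioles, 95.6% and 65% in glomeruli, 98.6% and 78.8% in venules and 99.6% and 96.7% in peritubular capillaries. In whole kidney the shares were 11% and 1.5%, and the median of all counts was 2480763 and 5127985.5. CLP and sham mice of one time point always belonged to the same of these 2 sets, and all healthy libraries belonged to one.

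**Figure D1:**
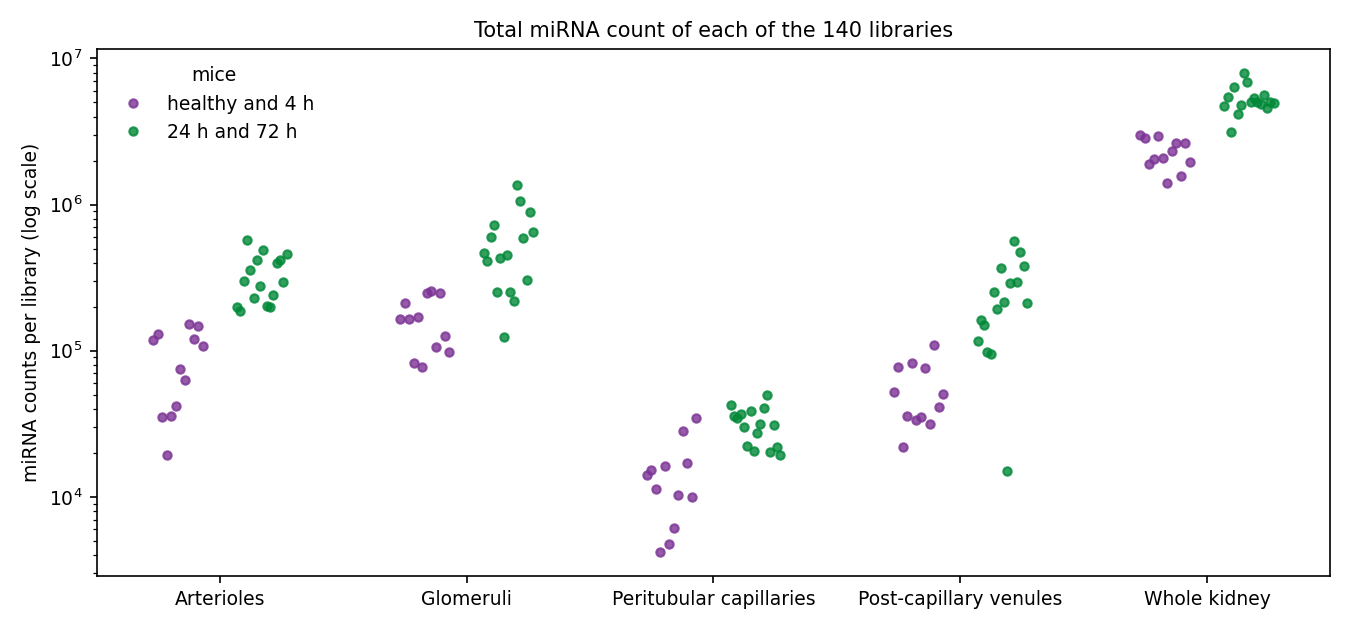
Total miRNA count of each library (points, log scale) in the 5 compartments, with healthy and 4 h mice apart from 24 h and 72 h mice. Whole kidney libraries held at least 1412288 miRNA counts and peritubular capillary libraries at most 49456.

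The first question was which miRNAs distinguish the microvascular compartments of a healthy kidney. In arterioles, miR-143-3p and miR-145a-5p, a pair made from neighbouring genes and known from smooth muscle, took the largest shares of the miRNA counts. These shares leave out the # entries, which took a mean of 97.4% of all counts in arterioles of the healthy and 4 h mice. miR-143-3p took 40.1% ± 5.04 (SD, n = 4) of arteriole miRNA counts and miR-145a-5p took 9.57% ± 1.09. Against the mean of the other 3 microdissected compartments of the same mice, miR-143-3p was higher by a log2 fold change of 3.86 (SE 0.162, edgeR adjusted p = 5.03e-35) and miR-145a-5p by 3.78 (edgeR adjusted p = 1.84e-33). miR-133a-3p, known from striated muscle, was higher by 4.62 (SE 0.61, edgeR adjusted p = 2.95e-09), at 5810 CPM ± 2530 against 369 CPM ± 154 in glomeruli. miR-126a-3p, the best known endothelial miRNA, was higher by 1.00 (SE 0.133, edgeR adjusted p = 3.23e-09) but did not set arterioles apart from glomeruli. Its CPM was nearly equal in these compartments. It took 2.83% ± 0.498 of miRNA counts in arterioles, 4.57% ± 0.546 in glomeruli and 2.9% ± 0.437 in venules. In GRCm38.p6, Mir143 lies on chromosome 18 at 61649196 to 61649258 and Mir145a at 61647825 to 61647894, neither inside another annotated gene.

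Of 383 miRNAs tested, 57 passed in arterioles, 35 higher and 22 lower (edgeR quasi-likelihood test with the mouse as a block, adjusted p under 0.05; with DESeq2 27 higher and 30 lower). All 4 tested members of the smooth muscle list were higher (fry adjusted p = 6.65e-29), among them miR-145a-3p (3.21) and miR-143-5p (4.08). In the endothelial list, 7 of 9 tested members were higher, including miR-23a-3p (1.59), miR-27a-3p (1.59) and miR-24-3p (1.12), and miR-221-3p (-1.11) and miR-222-3p (-1.66), which are also found outside endothelium, were lower (fry adjusted p = 3.03e-08). Adjusted over the list alone, the counts were the same 7 and 2. The epithelial miR-200 family was lower as a set (fry adjusted p = 3.83e-06) with 4 of 8 tested members past the threshold and 6 when adjusted over the list alone. Its members miR-429-3p, miR-200a-3p and miR-200b-3p had log2 fold changes of -3.01, -2.75 and -2.7. The tubular list of miR-192, miR-194 and miR-215 was lower too (fry adjusted p = 0.000286; 2 of 5 members, 3 when adjusted over the list alone), with miR-192-5p at -2.07. The inflammation list (fry adjusted p = 4.07e-06) was lower with miR-221-3p and miR-222-3p as its 2 called members out of 11. miR-100-5p (2.84), miR-140-3p (2.53) and miR-99a-5p (1.01) were further miRNAs higher in arterioles. miR-92a-3p (-1.2), miR-107-3p (-1.05), miR-378a-3p (-0.97) and miR-455-3p (-2.08) were lower.

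Glomeruli were marked by miR-23b-3p and by a pair of miRNAs of one X-linked cluster, miR-322-3p and miR-351-5p. miR-23b-3p reached 96400 CPM ± 15000 in glomeruli, against 37700 CPM ± 6980 in arterioles and 13200 CPM ± 1920 in peritubular capillaries, a log2 fold change of 2.22 over the other 3 compartments (SE 0.116, edgeR adjusted p = 8.03e-29). miR-322-3p stood at 8160 CPM ± 1110 against 184 CPM ± 56.3 in arterioles (log2 fold change 4.74, SE 0.485, edgeR adjusted p = 4.24e-13), and miR-351-5p had a log2 fold change of 4.01. miR-30a-5p, of a family needed by podocytes, was higher by 1.2 (SE 0.145, edgeR adjusted p = 1.84e-10). miR-21a-5p, known from injury and fibrosis, was lowest here, at 7080 CPM ± 1250 (log2 fold change -1.08, SE 0.185, edgeR adjusted p = 2.91e-06). Mir23b lies on chromosome 13 at 63300484 to 63300557 in GRCm38.p6, within an intron of 2010111I01Rik on the same strand.

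In all, 82 miRNAs passed in glomeruli, 64 higher and 18 lower. With DESeq2 it was 35 higher and 30 lower, and without healthy replicate 3 edgeR called 54, 43 higher and 11 lower. Of the endothelial list, 7 of 9 tested members were higher and 0 lower (fry adjusted p = 2.99e-17; 7 and 1 when adjusted over the list alone), among them miR-126a-3p (0.99), miR-27b-3p (1.5) and miR-24-3p (1.77). Of the miR-30 family, 6 of 11 were higher (fry adjusted p = 6.23e-11; 8 higher and 1 lower when adjusted over the list alone), including miR-30d-5p (1.06) and miR-30a-3p (1.26). Sets with fewer called members were higher as well: the Dlk1-Dio3 cluster of imprinted miRNAs (2 of 10, 3 when adjusted over the list alone; fry adjusted p = 1.02e-07), the 17-92 cluster (1 of 8; fry adjusted p = 0.000949), the Hox cluster (1 of 7, 0 when adjusted over the list alone; fry adjusted p = 0.00201) and the inflammation list (1 of 11; fry adjusted p = 0.0265), where the called member was miR-132-3p (2.01). miR-125a-5p (1.41), miR-26a-5p (0.87) and miR-652-3p (1.59) were also higher. The lower miRNAs included miR-99a-5p (-0.9), miR-203-3p (-1.66), miR-107-3p (-0.86), miR-22-3p (-0.81) and miR-140-3p (-0.56).

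Peritubular capillary samples held more of the miRNAs known from tubular epithelium, and less of the endothelial ones, than the mean of the other 3 compartments. miR-192-5p, abundant in renal tubules, was at 4630 CPM ± 818 in them and at 625 CPM ± 482 in arterioles (log2 fold change over the other 3 compartments 2.1, SE 0.34, edgeR adjusted p = 4.66e-07). miR-429-3p, of the epithelial miR-200 family, was higher by 2.66 (SE 0.332, edgeR adjusted p = 4.39e-10). The endothelial miR-126a-3p was at 12500 CPM ± 1580, against 46000 CPM ± 5470 in arterioles and 45900 CPM ± 5480 in glomeruli (log2 fold change -1.52, SE 0.155, edgeR adjusted p = 2.26e-13). miR-107-3p, encoded in a gene of coenzyme A synthesis, was higher by 2.07 (SE 0.167, edgeR adjusted p = 7.98e-18). These libraries held the fewest miRNA counts, and miR-6240, a poorly characterised entry, took 7.3% ± 3.81 of their miRNA counts.

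Of 87 miRNAs past the threshold in peritubular capillaries, 34 were higher and 53 lower. The tubular list (2 of 5 higher, 3 when adjusted over the list alone; fry adjusted p = 4.07e-06) and the miR-200 family (3 of 8 higher, 4 when adjusted over the list alone; fry adjusted p = 2.97e-05) were higher, with miR-200b-3p at 2.49 and miR-200a-3p at 1.69. In the endothelial list, 7 of 9 were lower, such as miR-23b-3p (-1.6), miR-23a-3p (-1.69) and miR-126a-5p (-1.93), and miR-221-3p (0.99) and miR-222-3p (1.15) were higher (fry adjusted p = 9.85e-14). All 4 smooth muscle members were lower (fry adjusted p = 5.52e-17), as were 5 of 7 erythroid members (6 when adjusted over the list alone; fry adjusted p = 5.8e-07; 4 of 6 with miR-486a-5p and miR-486b-5p counted once), 3 of 6 leukocyte members (fry adjusted p = 0.000264) and 2 of 10 Dlk1-Dio3 members (fry adjusted p = 0.000576). miR-127-3p, of that cluster, had 0 counts in the 4 peritubular capillary libraries and 806 CPM ± 458 in glomeruli. Further miRNAs higher here were miR-378a-3p (1.33), miR-203-3p (2.12), miR-455-3p (1.86), miR-22-3p (1.05) and miR-21a-5p (0.68).

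Post-capillary venules held more of the miRNAs of red blood cells than the other vessels. miR-451a, made in erythroid cells, was at 15400 CPM ± 7350 in venules and 4480 CPM ± 1010 in glomeruli (log2 fold change over the other 3 compartments 1.8, SE 0.377, edgeR adjusted p = 0.000229). miR-486a-5p and miR-486b-5p, also erythroid, were each higher by 2.2 (SE 0.283, edgeR adjusted p = 4.68e-09). Their sequences are near identical and their counts nearly equal, so the copies cannot be told apart. Of the erythroid list, 6 of 7 members were higher (fry adjusted p = 3.67e-10), or 5 of 6 with this pair counted once (fry adjusted p = 1.31e-09).

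A total of 39 miRNAs passed in venules, 23 higher and 16 lower. With RLE size factors 29 were higher and 9 lower, and without healthy replicate 3 edgeR called 23, 13 higher and 10 lower. The miR-200 family was higher (3 of 8, 4 when adjusted over the list alone; fry adjusted p = 0.000121), led by miR-429-3p (1.37) and miR-200c-3p (1.73). The leukocyte list was higher as a set with 0 of 6 members past the edgeR threshold (fry adjusted p = 0.00547), as was the tubular list with 0 of 5 (1 when adjusted over the list alone; fry adjusted p = 0.0331). The inflammation list (1 of 11, miR-222-3p at 1.08; fry adjusted p = 0.000864) and the injury list (1 of 8, miR-214-3p at 1.02, and 2 when adjusted over the list alone; fry adjusted p = 0.0334) were higher. The endothelial list was lower on balance, with 5 of 9 members lower and 1 higher (6 and 2 when adjusted over the list alone; fry adjusted p = 2.39e-05). Its members miR-23b-3p and miR-27b-3p were at -1.04 and -0.85, and miR-126a-3p was lower by less (-0.48, edgeR adjusted p = 0.0189; 0.0842 with DESeq2). Lower sets were the smooth muscle list (2 of 4, 3 when adjusted over the list alone; fry adjusted p = 2.25e-06), the Hox cluster (1 of 7, 4 when adjusted over the list alone; fry adjusted p = 3.89e-05), the miR-30 family (3 of 11, 5 when adjusted over the list alone; fry adjusted p = 0.000134) and the miR-29 family (1 of 3; fry adjusted p = 0.0489). miR-24-3p (-1.17) was lower and missed the threshold without healthy replicate 1 (edgeR adjusted p = 0.0555), and miR-126a-3p missed it without replicate 1, 3 or 4 (0.0963, 0.0863 and 0.425).

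**Figure D2:**
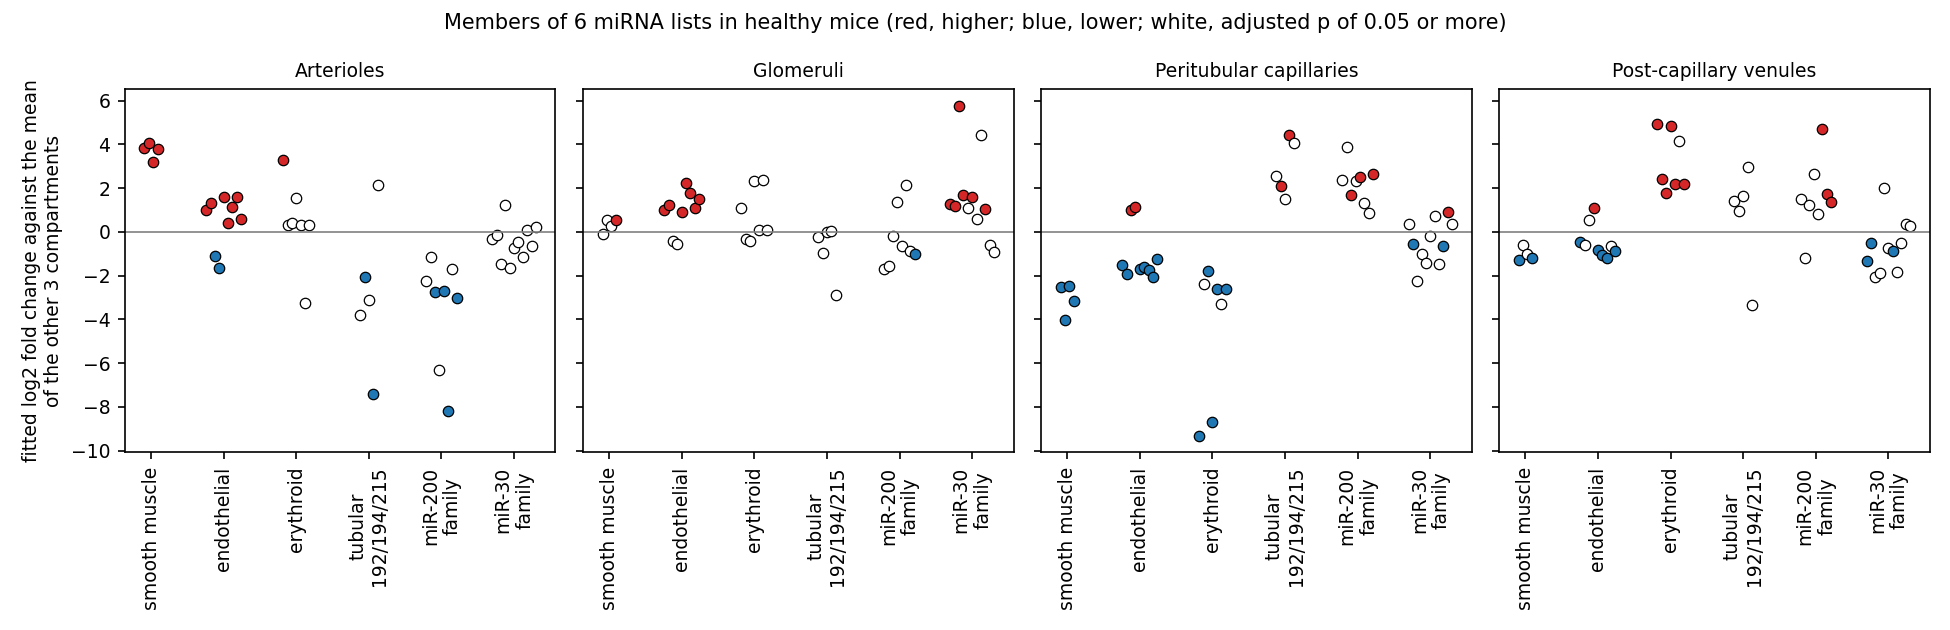
Fitted log2 fold change of each tested member of 6 miRNA lists in healthy mice, each compartment against the mean of the other 3 (red, higher; blue, lower; white, adjusted p of 0.05 or more; members with 0 counts in a compartment sit at values that depend on the prior count). The 4 smooth muscle members lie high in arterioles and low in peritubular capillaries.

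Whole kidney, in the same healthy mice, was richer than the microdissected vessels in epithelial miRNAs. miR-192-5p was at 7700 CPM ± 538, against 4750 CPM in peritubular capillaries and 690 CPM in arterioles under one common scaling (log2 fold change over the 4 microdissected compartments 2.24, SE 0.267, edgeR adjusted p = 6.51e-08). miR-429-3p (2.41) and miR-200b-3p (2.73) were higher too, as was miR-30a-5p (0.94) and, most of the miR-30 family, miR-30e-3p (2.43). Lower were miR-320-3p (-2.98), miR-423-5p (-2.82), miR-744-5p (-4.97) and 5 poorly characterised entries: miR-5119 (-10.23, edgeR adjusted p = 8.3e-13), which tied with miR-320-3p for the smallest adjusted p, miR-5106 (-9.98), miR-5124a (-9.47), miR-6240 (-5.1) and miR-5099 (-3.38). miR-5119 was at 0.736 CPM ± 0.318 in whole kidney and 3470 CPM ± 908 in peritubular capillaries. Of 242 miRNAs tested, 107 passed, 71 higher and 36 lower, and with DESeq2 the split was 46 higher and 61 lower.

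The called lists in whole kidney were the tubular list (3 of 3 higher; fry adjusted p = 3.89e-05), the miR-200 family (6 of 7, 7 when adjusted over the list alone; fry adjusted p = 1.36e-07), the miR-30 family (7 of 9; fry adjusted p = 9.68e-08), the inflammation list (4 of 8; fry adjusted p = 5.41e-06), the Hox cluster (3 of 7, 4 when adjusted over the list alone; fry adjusted p = 1.42e-05) and the let-7 family (2 of 9; fry adjusted p = 0.00195). Lower were the smooth muscle list (2 of 4, 3 when adjusted over the list alone; fry adjusted p = 4.98e-05) and the erythroid list (3 of 6, 4 when adjusted over the list alone; fry adjusted p = 0.00211; 2 of 5 with miR-486a-5p and miR-486b-5p counted once). The endothelial list went both ways, with 2 members higher and 3 lower (fry adjusted p = 0.279 one way and 3.25e-06 in either direction). The injury list also went both ways, with miR-34a-5p (2.25) and miR-21a-5p (0.46) higher and miR-214-3p (-2.36) lower (fry adjusted p = 0.00301 in either direction). The median log2 fold change of all miRNAs tested here lay above 0 and above that of miR-21a-5p. fry does not compare members with other miRNAs. Lists called higher, such as the let-7 family, therefore need not be higher relative to other miRNAs. Whole kidney was not microdissected, so tissue and collection method cannot be separated in these differences.

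The central question was how sepsis changed miRNAs in each compartment. miR-21a-5p, a miRNA induced in injured kidney, was the one called most often: it was higher in CLP than in sham mice in 6 of the 15 comparisons and had a positive log2 fold change in all 15 with TMM scaling. Scaled to the # entries, it turned to -0.06 in glomeruli and -0.33 in whole kidney at 4 h and to -0.63 in peritubular capillaries at 72 h, 1 of the 6. That scaling ended 4 of the 6 calls, this one and those in glomeruli at 72 h (0.92), peritubular capillaries at 24 h (0.92) and venules at 72 h (1.16), and left the 2 in whole kidney. miR-21a-5p lay above the median of all miRNAs in each of the 15 under that scaling. Such scaling moves all miRNAs of a library by one factor, so this is no separate test of the TMM result. At 24 h miR-21a-5p was at 77600 CPM ± 13300 in CLP and 38000 CPM ± 3100 in sham peritubular capillaries (log2 fold change 1.03, SE 0.185, edgeR adjusted p = 0.000652). At 72 h it was at 24800 CPM ± 2600 against 11400 CPM ± 3520 in glomeruli (1.12, SE 0.201, edgeR adjusted p = 0.00114) and at 67700 CPM ± 16100 against 31700 CPM ± 8460 in venules (1.09, SE 0.238, edgeR adjusted p = 0.00832). In each of these, 4 of 4 CLP libraries lay above every sham library. The same held in arterioles at 72 h and in glomeruli and venules at 24 h, where miR-21a-5p was not called. Mir21a lies on chromosome 11 at 86584067 to 86584158 in GRCm38.p6, where it overlaps an exon of the protein-coding gene Vmp1 on the same strand.

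In arterioles miR-21a-5p was at 16300 CPM ± 6230 against 11200 CPM ± 864 at 24 h (log2 fold change 0.54) and at 18500 CPM ± 1740 against 11200 CPM ± 555 at 72 h (0.72), with edgeR adjusted p of 1 and 0.336 (unadjusted 0.0246 and 0.00363). At 4 h its log2 fold change lay between 0.2 in whole kidney and 0.43 in arterioles, with no edgeR adjusted p under 0.525. The test of whether its change differed between the 4 microdissected compartments gave edgeR adjusted p of 0.922 at 4 h, 1 at 24 h and 1 at 72 h. Averaged per mouse over these compartments, a comparison chosen after the data were seen, it was higher by 0.38 at 4 h, 0.7 at 24 h and 0.97 at 72 h (limma adjusted p = 0.125, 0.000125 and 6.5e-08). A test of that average across time points gave a limma p of 0.003 unadjusted and 0.466 adjusted over all miRNAs. That test crosses the 2 sets of libraries, so a change of this response with time is neither shown nor excluded.

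**Figure D3:**
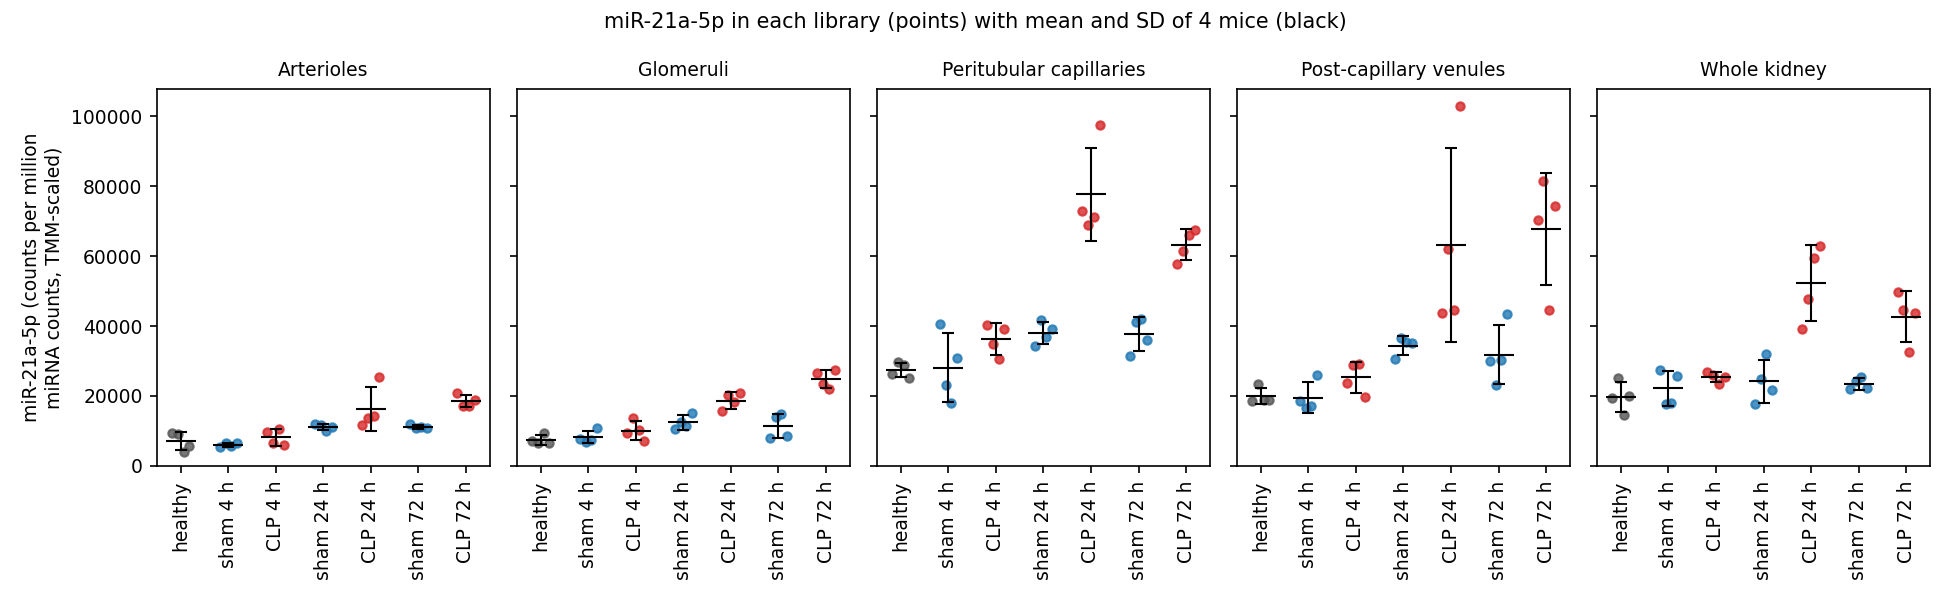
miR-21a-5p in each library (points), in CPM, by group and compartment, with the mean and SD of 4 mice in black. At 72 h, CLP and sham glomeruli averaged 24800 and 11400 CPM.

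Over the 15 comparisons of CLP with sham, edgeR made 27 calls on 19 named miRNAs, in 9 comparisons, or 26 calls on 18 with miR-199a-3p and miR-199b-3p, which share a sequence, as one. The 12 comparisons in microdissected vessels gave 12 of the 27 calls (11 of the 26), in 6 comparisons. Of the fixed miRNA lists, 0 of 216 set tests passed (fry, smallest adjusted p = 0.128; 18 at an unadjusted p under 0.05), so no list can be said to have risen or fallen with CLP. That smallest p belonged to the tubular list in whole kidney at 72 h, where miR-192-5p stood at 7190 CPM ± 1180 in CLP and 9820 CPM ± 1380 in sham mice (log2 fold change -0.45, edgeR adjusted p = 0.332).

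In glomeruli at 4 h, miR-199a-3p and miR-199b-3p, a pair with the same mature sequence made in mesenchymal cells, were lower in CLP mice. Both stood at 335 CPM ± 122 against 916 CPM ± 220 (log2 fold change -1.44, SE 0.303, edgeR adjusted p = 0.00656), with 4 of 4 CLP libraries below every sham library. They were the 2 calls among 338 miRNAs tested, and they count as 1 measurement. Erythroid miRNAs of the same samples gave 0 calls over all miRNAs by edgeR (4 of 7 higher when adjusted over the list alone, and 0 of 6 with miR-486a-5p and miR-486b-5p counted once; fry adjusted p = 0.205), with miR-486a-5p at 22900 CPM ± 11800 against 14100 CPM ± 5920. DESeq2 called 15 miRNAs in this comparison, and edgeR called 10 without CLP replicate 2 and 4 without sham replicate 3. With the spread estimated from the 8 libraries compared, edgeR called 0 (34 at an unadjusted p under 0.05).

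In glomeruli at 24 h, 0 of 338 miRNAs passed with edgeR, 36 had an unadjusted p under 0.05, and DESeq2 called 10. Without CLP replicate 3 edgeR called 8, without CLP replicate 1 it called 2 and without sham replicate 3 it called 1, and with no low-count filter it called 3. miR-744-5p (log2 fold change 0.99, edgeR adjusted p = 0.107) and miR-132-3p (0.91, edgeR adjusted p = 0.132) had the smallest p. At 72 h, miR-132-3p, a miRNA induced by CREB signalling, was higher in CLP glomeruli, at 4490 CPM ± 1120 against 2020 CPM ± 490 (1.15, SE 0.255, edgeR adjusted p = 0.0131). With miR-21a-5p it made the 2 calls. It missed the threshold without CLP replicate 4 (edgeR adjusted p = 0.141) or without sham replicate 2 (0.123), while miR-21a-5p passed without any one library.

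In peritubular capillaries, miR-21a-5p was the only call at 24 h (201 tested; 2 calls with DESeq2) and missed the threshold without sham replicate 1 (edgeR adjusted p = 0.116) or sham replicate 4 (0.0567). At 72 h it was at 63200 CPM ± 4400 against 37700 CPM ± 4880 (log2 fold change 0.75, SE 0.184, edgeR adjusted p = 0.0278). miR-194-2-3p, of the tubular list, had 0 counts in the 4 CLP libraries and 86 counts in the 4 sham libraries, at least 17.8-fold lower (edgeR adjusted p = 0.0278; floor of 3 counts over the group). Other members of that list did not fall with it: miR-192-5p stood at a log2 fold change of 0.06, miR-194-5p at 0.11 and miR-215-5p at 1.49 (edgeR adjusted p = 0.993, 0.997 and 0.894). Without any one of the 8 libraries, miR-21a-5p missed the threshold (edgeR adjusted p between 0.0711 and 0.35), and miR-194-2-3p did so without any one CLP library or without sham replicate 1 or 2 (0.0711 to 0.17). The number of miRNA counts per count of the # entries was also lower in CLP than in sham peritubular capillaries at 72 h, by a log2 difference of -1.34, and scaling to these entries gave 49 calls, all lower. At 4 h, 0 miRNAs passed with edgeR and 0 with DESeq2, and 14 had an unadjusted p under 0.05. miR-30e-3p stood at 4700 CPM ± 3130 against 1640 CPM ± 1040 (log2 fold change 1.46, edgeR adjusted p = 0.462), and miR-139-5p had 34 counts in CLP and 0 in sham libraries.

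In arterioles at 4 h, miR-429-3p had 0 counts in the 4 sham libraries and 55 counts in 3 of the 4 CLP libraries, at least 8.14-fold higher (edgeR adjusted p = 0.0232; 278 tested; floor of 3 counts over the group). Healthy arterioles held it at 173 CPM ± 106, and CLP arterioles at 125 CPM ± 91.5. It missed the threshold without CLP replicate 4 or without any one sham library (edgeR adjusted p between 0.0676 and 0.145), and with the spread from the 8 libraries compared edgeR called 0. DESeq2 called 4 at 4 h, 1 higher and 3 lower. At 24 h and 72 h, edgeR called 0 miRNAs in arterioles, 4 and 9 had an unadjusted p under 0.05, and DESeq2 called 0 and 1. The smallest p at 24 h belonged to miR-326-3p, with 85 counts in CLP and 0 in sham libraries (edgeR adjusted p = 0.765), and to miR-27a-5p, with 15 counts and 0 (1). At 72 h miR-193a-3p stood at 11.2 CPM ± 12.4 against 141 CPM ± 69.9 (log2 fold change -3.58, edgeR adjusted p = 0.336) and miR-208a-5p had 76 counts in CLP and 1 in sham libraries (edgeR adjusted p = 0.336).

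In post-capillary venules at 72 h, miR-21a-5p was the 1 higher call of 4 (285 tested). The 3 lower calls were miR-6240, miR-2137 and miR-8109, poorly characterised entries whose excess in sham mice came from one library. The other sham libraries held 135 to 244 counts of miR-6240, 79 to 189 of miR-2137 and 0 to 12 of miR-8109. In sham replicate 2, these miRNAs took 6732 of 15148 counts, or 44.4% (exact 95% interval 43.6 to 45.2). Without that library edgeR called 0 miRNAs, the log2 fold changes of the 3 were 0.09, -0.04 and 1.18, and miR-21a-5p stood at 1.00 (edgeR adjusted p = 0.0762). Without sham replicate 1 or sham replicate 4 edgeR called 7, with the spread from the 8 libraries compared it called 0, and DESeq2 called 1. At 4 h and 24 h, edgeR called 0 miRNAs, 18 and 5 had an unadjusted p under 0.05, and DESeq2 called 2 and 1. The smallest p at 4 h belonged to miR-874-5p (80 counts in CLP and 1 in sham libraries, edgeR adjusted p = 0.062) and miR-30c-1-3p (1 count and 67, 0.148). At 24 h miR-21a-5p was at 63200 CPM ± 27700 against 34400 CPM ± 2670 (0.88, edgeR adjusted p = 0.263) and miR-351-5p at 299 CPM ± 105 against 689 CPM ± 382 (-1.22, edgeR adjusted p = 0.983).

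Whole kidney, with the most miRNA counts, gave 15 of the 27 calls. At 4 h, miR-21a-3p, the other strand of the miR-21a hairpin, was the 1 call of 542 tested, at 61 CPM ± 24.5 in CLP against 23.6 CPM ± 4.01 in sham mice (log2 fold change 1.35, SE 0.257, edgeR adjusted p = 0.00684). Without CLP replicate 1, CLP replicate 2 or sham replicate 3, edgeR called 0 at 4 h, as it did with the spread from the 8 libraries compared, and DESeq2 called 3. At 24 h edgeR called 1 with that spread, 1 without CLP replicate 4 or sham replicate 1 and 2 without sham replicate 2 or 3. At 24 h both strands were higher: miR-21a-5p at 52300 CPM ± 11000 against 24200 CPM ± 6080 (1.11, SE 0.18, edgeR adjusted p = 0.00052) and miR-21a-3p at 47.3 CPM ± 12.7 against 21.7 CPM ± 5.41 (1.13, SE 0.242, edgeR adjusted p = 0.0174). miR-2137 was higher by 1.82 (edgeR adjusted p = 0.0211) and miR-3061-3p lower by a log2 fold change of -1.1 (edgeR adjusted p = 0.0211). Without CLP replicate 4, miR-2137 stood at 0.99 (edgeR adjusted p = 0.407).

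At 72 h, 10 miRNAs were called in whole kidney, 9 higher and 1 lower. DESeq2 called 22 (16 higher, 6 lower), edgeR called 30 with the spread from the 8 libraries compared (17 and 13), and scaling to the # entries, which moved the median of all miRNAs to 0.87, gave 277, all higher. miR-1247-5p, at 42 CPM ± 8.72 in sham mice, was higher in CLP mice (log2 fold change 1.42, SE 0.277, edgeR adjusted p = 0.00506). miR-21a-5p (0.86, SE 0.18, edgeR adjusted p = 0.0079) and miR-21a-3p (0.99, SE 0.242, edgeR adjusted p = 0.0213) were again higher. miR-223-5p, the minor strand of a myeloid miRNA, was higher by 1.52 (SE 0.326, edgeR adjusted p = 0.00843) at 8.39 CPM ± 2.71 against 2.9 CPM ± 0.71, and the major strand miR-223-3p was at 242 CPM ± 58.4 against 153 CPM ± 17.7 (0.66, edgeR adjusted p = 0.0547). miR-6538 was higher by 4.66 (edgeR adjusted p = 0.000459), at 18.8 CPM ± 15.3 against 0.717 CPM ± 0.409. The other higher calls were miR-455-3p (0.75), miR-139-5p (0.65), miR-92b-3p (0.64) and miR-17-5p (0.59), the last of the growth-related 17-92 cluster, and miR-3105-3p was the lower one (-0.81). Each called miRNA had 4 of 4 CLP libraries on one side of every sham library. Mir1247 lies on chromosome 12 at 110278048 to 110278129, in an exon of the long non-coding RNA Dio3os, and Mir223 on chromosome X at 96242817 to 96242926, in an exon of F630028O10Rik (GRCm38.p6).

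In the injury list, 2 of 9 members passed at 72 h over all miRNAs and 4 when adjusted over the list alone, the further ones being miR-214-3p (0.47, edgeR adjusted p = 0.1) and miR-199a-5p (0.34, edgeR adjusted p = 0.273). In the leukocyte list 1 of 7 passed, and 2 when adjusted over the list alone. Neither list passed as a set (fry adjusted p = 0.292 and 0.324). Without 1 library the number of calls at 72 h ranged from 2 to 15: it was 2 without CLP replicate 2 or sham replicate 1, 4 without CLP replicate 1, sham replicate 2 or sham replicate 4, 5 without CLP replicate 4 and 6 without sham replicate 3. There miR-21a-5p missed the threshold without CLP replicate 1 (0.0546), CLP replicate 2 (0.0619) or sham replicate 1 (edgeR adjusted p = 0.0557). The ratio of miRNA counts to counts of the # entries was higher in CLP whole kidney at 72 h, by a log2 difference of 0.82.

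Whether the response to CLP differed between compartments was tested within mice. At 4 h, 1 of 383 miRNAs passed, miR-429-3p (edgeR adjusted p = 0.00949), whose change was positive in arterioles and lay between 0.01 in venules and 0.64 in peritubular capillaries elsewhere. It missed the threshold with the spread taken from the 32 libraries of that time alone, where edgeR called 0, and 0 miRNAs passed without CLP replicate 4 or sham replicate 1, 2 or 4. At 24 h and 72 h, 0 passed with edgeR, 13 and 16 had an unadjusted p under 0.05, and DESeq2 called 1 and 2. The smallest p at 24 h belonged to miR-193a-3p (edgeR adjusted p = 0.477) and miR-15b-5p (0.961), and at 72 h to miR-5119 and miR-144-3p (both 0.485). Whether the per-mouse average response differed between times gave 0 calls with limma (17 at an unadjusted p under 0.05; smallest adjusted p 0.094 for miR-429-3p). That test crosses the 2 sets of libraries. Between 72 h and 24 h, within one set, limma called 0 (6 at an unadjusted p under 0.05), and the smallest p belonged to miR-193a-3p and miR-142a-3p (-1.98 and 1.73, limma adjusted p = 0.995).

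Sham mice were compared with healthy mice on the per-mouse average of the 4 microdissected compartments, to see what surgery alone changed. Several let-7 miRNAs, a family known from differentiation, were higher in sham mice: let-7c-5p by a log2 fold change of 1.13 (limma adjusted p = 9.83e-09), let-7b-5p by 1.38, let-7g-5p by 1.14 and let-7i-5p by 1.09. miR-196b-5p (1.06) and miR-196a-5p (0.83) from the Hox clusters, miR-140-5p (1.91), miR-28a-5p (1.69), miR-25-3p (0.62) and miR-21a-5p (0.47) were higher as well. miR-26a-5p (-0.47), miR-26b-5p (-0.36), miR-320-3p (-0.61), miR-423-5p (-0.73), miR-423-3p (-0.69), miR-140-3p (-0.46), miR-378a-3p (-0.33), miR-19b-3p (-0.62), miR-5099 (-0.93) and miR-6244 (-1.89) were lower. In all 66 of 383 passed, 54 higher and 12 lower, and with the size factors of DESeq2 (RLE) the split was 33 and 20. Without healthy replicate 3 or 4, limma called 43 and 40. In simulated data 18.8% of the calls of this comparison were false, above the 5% aimed at. Within the one set that holds both groups, sham mice at 4 h differed from healthy mice in 1 miRNA, miR-429-3p (-1.22, limma adjusted p = 0.0036), and let-7c-5p stood at -0.14. The arteriole libraries of these sham mice held no count of miR-429-3p and enter this average. The call is therefore not separate from the arteriole result at 4 h. Across the sets, sham mice at 24 h and 72 h differed in 125. In glomeruli let-7c-5p was at 4050 CPM ± 1370 in healthy, 5350 CPM ± 1850 in sham 4 h, 13000 CPM ± 1440 in sham 24 h and 13100 CPM ± 2700 in sham 72 h mice, so that the set of libraries and the later times cannot be told apart.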

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

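The tests of explanations and of the ratio to the # entries in this part were chosen after the results were seen, except the thinning of sham libraries, and the comparison between compartments was planned.

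A library far from the others of its group was sought in 107 groups, and chance marks about 1 in 20 groups. miR-21a-5p stood apart in arteriole sham 72 h replicate 1 (log2 CPM 13.56 against 13.41 to 13.43; gap over range 0.865) and in peritubular capillary CLP 24 h replicate 4 (16.57 against 16.08 to 16.16; 0.839). miR-429-3p stood apart in arteriole CLP 4 h replicate 3 (3.12 against 7 to 7.79; 0.831), the 1 CLP library without a count of it. miR-455-3p did so in whole kidney CLP 72 h replicate 1 (11.06 against 10.88 to 10.9; 0.902). In venules, miR-8109 stood apart in CLP 72 h replicate 1 (gap over range 1, with the other 3 libraries at 0), and in sham 72 h replicate 2 miR-6240 (18.73 against 8.8 to 10.17; 0.862) and miR-8109 (0.895) did.

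The CLP effect on miR-429-3p at 4 h differed between compartments (edgeR adjusted p = 0.00949). It rests on 0 counts in the sham arterioles.

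The # entries lie outside the comparisons. The log2 ratio of miRNA counts to their counts was lower in CLP than in sham peritubular capillaries at 72 h, by -1.34, and higher in whole kidney at 72 h, by 0.82. In both, the CLP and sham libraries did not overlap (exact permutation test, two-sided p = 0.0286, the smallest that 4 against 4 allows; adjusted over 15 comparisons 0.214). What sets this ratio was not tested.

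Of 66 miRNAs called between sham and healthy mice, most may mark the set of libraries: in sham 4 h mice, which share a set with the healthy ones, they moved in the called direction by a median of 0.12 (log2; 95% 0.04 to 0.26), and in sham 24 h and 72 h mice, of the other set, by 1.35 (1.07 to 1.55). An effect of surgery alike at all times is argued against by the upper limit of 0.26. That limit is of a median over miRNAs measured in the same mice, which are not independent. The 66 were also picked from the average of all sham times, where 24 h and 72 h together outweigh 4 h. This choice favours a larger change at the later times. The larger miRNA counts of most sham libraries as the whole cause are argued against too, since with sham libraries thinned to the miRNA counts of healthy ones the median was still 0.88 (draws 0.84 to 0.93, unthinned 1.05), with 48.5 calls in the median draw. A change that appears at 24 h or later cannot be told apart from the set, as 0 sets hold both healthy mice and sham mice of those times.

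The calls of 3 miRNAs as lower in CLP venules at 72 h likely come from 1 sham library with few counts, replicate 2, which held 70066 counts in all entries against a median of 1165693 in the other venule libraries of its set. Without it 0 of the 3 were left past the threshold. The median of their log2 fold changes without it was 0.09, which argues against a fall of these miRNAs in CLP venules. Why this library is rich in miR-6240, miR-2137 and miR-8109 was not tested.

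In healthy peritubular capillaries, tubular and epithelial miRNAs were higher and endothelial ones lower. The low number of miRNA counts by itself, as counting error, is argued against as the cause: with all libraries of a mouse thinned to its peritubular capillary library, the median of the 13 tubular and epithelial members was 2.03 (draws 1.5 to 2.38) against 2.06 unthinned, and that of the 9 endothelial members -1.44 (draws -1.51 to -1.36) against -1.62, with the members fixed before thinning and no low-count filter. Thinning keeps the shares of miRNAs in a library on average. It therefore cannot test a small amount of RNA or the large share of the # entries as a cause. Tubular epithelium in the dissected tissue stays open as a candidate source. The 66 other miRNAs that were higher in whole kidney than in the other 3 compartments of sham mice had a median of 0.38 here, with a 95% interval of -0.2 to 0.76 that includes 0, and 36 were above 0. This median lay at percentile 100 among 10000 random lists. That percentile cannot decide, since these miRNAs were picked against the same 3 compartments they are compared with here. miRNAs low in those 3 can score high with or without tubular epithelium, and the random lists were not picked in this way. No biological explanation, such as miRNAs of the capillary wall itself, was tested.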

How the results depend on the processing

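The scaling to the # entries, the comparisons within or across sets of libraries, the per-mouse averages of CLP against sham and the fit without one venule library were chosen after the data were seen. Of the settings tried on counts of calls and of called lists, 267 left the count within 1.5 times of the reported one, 61 moved it further, 33 gave calls where there were none and 37 ended them. Of the settings tried on single miRNAs, 1938 kept direction and side of the threshold, 145 ended a call, 18 made one and 17 turned the direction. Except where said, the cause was not tested.

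With DESeq2's Wald test CLP against sham gave 4 calls in arterioles at 4 h (1 higher, 3 lower) and 1 at 72 h, 15 in glomeruli at 4 h (4 and 11) and 10 at 24 h (9 and 1), 2 in peritubular capillaries at 24 h, 2, 1 and 1 in venules at 4 h, 24 h and 72 h, and 3 and 22 in whole kidney at 4 h and 72 h. DESeq2's likelihood ratio test for a difference between compartments gave 1 at 24 h and 2 at 72 h. With no low-count filter, which adds miRNAs near 0, there was 1 in arterioles at 72 h, 10 and 3 in glomeruli at 4 h and 24 h, 1, 7 and 6 in peritubular capillaries and 2, 2 and 15 in venules at 4 h, 24 h and 72 h, and 7, 10 and 16 in whole kidney. The tests between compartments then gave 6, 2 and 9, and the average at 4 h gave 0.

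With the spread from the 8 libraries compared (fewer samples, fewer miRNAs tested), calls were 0 and 2 in arterioles at 4 h and 72 h, 0 in glomeruli at 4 h, 0 in venules at 72 h and 0, 1 and 30 in whole kidney at 4 h, 24 h and 72 h. With the 32 libraries of 4 h alone, the test between compartments gave 0. Without libraries under 1e+05 miRNA counts, venules gave 2 at 24 h and 0 at 72 h, the test between compartments 1 and 3, and at 72 h miR-6240 (0.17), miR-2137 (0.05) and miR-8109 (1.13) turned. This setting could not be run for arterioles and venules at 4 h, for peritubular capillaries, for the healthy comparisons or for the test between compartments at 4 h, and it removes no whole kidney library.

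Replicate numbers did not pair the mice: in 0 of 15 comparisons did every pair of deviations correlate above 0.1 (range -0.28 to 0.28), and in 0 did every CLP library correlate best with its own number. With the replicate block calls were 0 in peritubular capillaries at 72 h, 1 in venules at 72 h and 3 for the average at 4 h, and 1 list passed. With no replicate block for the mouse, the test between compartments gave 3 at 72 h. RLE size factors gave 0 calls for the average at 4 h and 1 list among the CLP comparisons. They split the calls 29 higher and 9 lower in healthy venules and 45 and 49 in whole kidney, where they moved the median log2 fold change of all miRNAs from 0.53 to 0.25, and DESeq2 split healthy glomeruli 35 and 30. A prior count of 0.5 gave 1 call between times and 5 for the average at 4 h.

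Averaged over all 7 groups, which uses more libraries, the compartments had 149 calls in arterioles (82 higher), 205 in glomeruli (160), 193 in peritubular capillaries (60) and 138 in venules (98). Sham 4 h mice alone gave 1 call against healthy ones, and let-7c-5p (-0.14), let-7i-5p (-0.03), let-7b-5p (-0.16), miR-196a-5p (-0.15), let-7g-5p (-0.01), miR-21a-5p (-0.06), miR-140-3p (0.07), miR-423-3p (0.01) and miR-6244 (0.17) turned. Sham 24 h and 72 h mice gave 125.

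Scaling to the # entries put the median of all miRNAs between -1.33 (peritubular capillaries, 72 h) and 0.87 (whole kidney, 72 h), so it gave 49 lower calls in the former and 277 higher ones in the latter, 9 of them among the 10 reported. It gave 0 calls in glomeruli at 4 h and 72 h, peritubular capillaries at 24 h and whole kidney at 4 h. miR-21a-5p turned to -0.06 in glomeruli at 4 h, -0.63 in peritubular capillaries at 72 h and -0.33 in whole kidney at 4 h. Relative to that median it lay between 0.06 and 1.17 above in the 15 comparisons. The scaling moves all miRNAs of a library by one factor, so this place above the median is no separate test of the TMM result.

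Without 1 library, calls ranged from 0 to 2 in arterioles at 4 h and were 0 at 24 h and 72 h. In glomeruli they ranged from 2 to 10, 0 to 8 and 1 to 2 at 4 h, 24 h and 72 h, in peritubular capillaries they were 0, 0 to 2 and 0 to 1, in venules 0 to 1, 0 to 1 and 0 to 7, and in whole kidney 0 to 2, 1 to 4 and 2 to 15. Healthy calls ranged from 39 to 53 in arterioles, 54 to 64 in glomeruli, 63 to 84 in peritubular capillaries, 23 to 30 in venules and 78 to 96 in whole kidney. The test between compartments gave 0 to 4, 0 and 0 to 3, the time test 0 to 1, sham against healthy 40 to 64 and the averages 0 to 3, 1 to 2 and 1. In venules at 72 h it was sham replicate 2 whose absence gave 0 calls and turned miR-6240 and miR-8109. Over the libraries left out, miR-6240 ranged from -7.62 to 0.09 and miR-8109 from -15.65 to 1.18.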

Other observations

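The ratios to the # entries and the counts over other splits in this part were chosen as tests after the results were seen, unlike the comparisons of miRNAs and lists. Some miRNA lists had too few tested members for a set test. miR-9-5p and miR-375-3p, of the neuronal and endocrine list, were higher in healthy whole kidney than in the microdissected compartments, by log2 fold changes of 3.61 (SE 0.527, edgeR adjusted p = 1.81e-06) and 2.07 (SE 0.727, edgeR adjusted p = 0.023). miR-9-5p was at 1880 CPM ± 467 in whole kidney and 55.9 CPM ± 26.9 in glomeruli. miR-210-3p, the 1 member of the hypoxia list tested in healthy compartments, was at 341 CPM ± 141 in healthy arterioles and 185 CPM ± 50.6 in glomeruli and was not called there over all miRNAs. In venules at 72 h its log2 fold change in CLP against sham mice was 1.48 (SE 0.648, edgeR adjusted p = 0.83). The hepatocyte miR-122-5p had 0 counts in healthy microdissected libraries.

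In peritubular capillaries at 24 h, 3 erythroid members were higher when adjusted over the list alone (2 with miR-486a-5p and miR-486b-5p counted once) and 0 over all miRNAs (fry adjusted p = 0.716). miR-451a was at 56500 CPM ± 93900 in CLP and 7170 CPM ± 3600 in sham mice, and its highest CLP library held 197000 CPM.

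The log2 ratio of miRNA counts to counts of the # entries was higher in CLP than in sham venules at 24 h by 0.95 and in whole kidney by 0.34 (exact permutation test, two-sided p = 0.0571 for each, adjusted 0.214), and in arterioles at 4 h by 0.83 (p = 0.114, exact).

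The splits of the same libraries that gave as many calls were counted, the real one included. Of the 35 splits of each comparison of CLP with sham, 1 gave as many in peritubular capillaries at 72 h (2 calls, highest other 1), in whole kidney at 24 h (4, highest other 1) and in whole kidney at 72 h (10, highest other 4). This is the smallest share that 35 splits can give and was not adjusted over the 15 comparisons. It argues against chance for each of these taken alone, without excluding it, and not for the 3 as picked from 15. In peritubular capillaries the margin was 1 call, and miR-21a-5p missed the threshold without any one of the 8 libraries. The other counts of calls give no such argument, as splits other than the real one gave as many: 8 splits in arterioles at 4 h (1 call, highest other 3), 2 in glomeruli at 4 h (2, highest other 4) and 2 at 72 h (2, highest other 2), 6 in peritubular capillaries at 24 h (1, highest other 2), 10 in venules at 72 h (4, highest other 6) and 17 in whole kidney at 4 h (1, highest other 48). The split with 48 sets CLP replicates 1 and 4 with sham replicates 2 and 3 against the rest, which points to a structure of these 8 samples other than their groups. Splits that keep 3 CLP mice together still carry an effect of CLP, such as the one with 2 calls in peritubular capillaries at 24 h, and these counts do not bear on single miRNAs such as miR-21a-5p. Where there were 0 calls, any split gives as many, so the 35 of 35 counted there test nothing. The highest others were 2 and 1 in arterioles at 24 h and 72 h, 8 in glomeruli at 24 h, 2 in peritubular capillaries at 4 h, and 3 and 0 in venules at 4 h and 24 h.

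For the healthy compartments, 1 of 40 drawn splits gave as many in arterioles (57 calls, highest other 50), glomeruli (82, highest other 60) and peritubular capillaries (87, highest other 39), and 1 of 100 in whole kidney (107, highest other 8). This argues against chance for these counts taken alone, without excluding it, and in arterioles the highest other count was near the real one. In venules 2 of 40 did (39, highest other 40). These draws swap compartments within mice and carry differences between the other compartments, so they do not decide the venule count. They do not bear on single results such as miR-486a-5p in venules (edgeR adjusted p = 4.68e-09). The tests between compartments had 19 of 35 at 4 h (1, highest other 6) and, with 0 calls that any split matches, 35 of 35 at 24 h and at 72 h (highest other 1 each). The averages had 9, 2 and 3 of 35 at 4 h, 24 h and 72 h (1 call each, highest others 2, 1 and 2), and the time test, also with 0 calls, 100 of 100 (highest other 26). The draws of the time test move mice between 4 h and the later times and so mix the 2 sets of libraries. Their calls can therefore carry the difference between the sets, which was not tested separately here. For sham against healthy it was 1 of 100 (66, highest other 54), and for sham 4 h against healthy 10 of 35 (1, highest other 4). The small share of splits in the former argues against chance without excluding it, and it does not separate surgery from the set of libraries.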
